A study of Mus musculus with 16 samples.

How the data were processed

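Total RNA from part of the lung of 16 female C57BL/6N mice had been hybridised to a mouse Illumina bead array, 1 array per mouse, with 4 mice in each of the groups wild type untreated, Prdm11 knockout untreated, wild type OVA challenged and Prdm11 knockout OVA challenged. Per the labels, the challenged mice had been sensitised intraperitoneally with OVA (10 µg) adsorbed to alum (2 mg) and exposed to 3 aerosol challenges of 1% OVA for 30 min each. The untreated mice carry no treatment in the labels, which leave open whether they had been sensitised. They were 22 weeks old and the challenged mice 35 weeks old, so that age and challenge cannot be separated. RNA had been extracted with Trizol and cleaned on a column, its quality had been judged by gel electrophoresis, and biotin-labelled cRNA had been prepared.

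The deposited values are intensity per probe on a linear scale, from GenomeStudio 2011.1 per the submitters' processing notes. Neither the normalization nor the background treatment is stated in the sources. Intensities ran from 0.1 to 45825.5. The sorted distributions of the 16 arrays were nearly identical, with a largest difference between arrays of 4.9 at the same rank, where the median was 242.8, and array medians of 85.4 to 86.5. The values were therefore used without further normalization. They were raised to a floor of 16, which applied to 1136 of 411152 values, and transformed to log2. Probes above the 40th percentile of the array on at least 4 arrays were tested, 17810 in all. The 40th percentile of each array, log2 6.24 to 6.25, also served as a gauge of background for named genes, chosen after the values were seen, and a difference is called a lower bound where the dimmer group lay above it in at most 1 of 4 mice. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 were not listed in the annotation. A total of 23962 were matched to the reference annotation by gene identifier, with 0 symbols updated. The mouse reference served for names and neighbouring genes only, and no coordinates are given. Prdm11 had 0 named probes.

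All 16 arrays were fitted in 1 linear model with a mean per group, using limma 3.58.1 in R 4.3.3 (lmFit and eBayes). The contrasts were challenged minus untreated in each genotype, knockout minus wild type in each treatment, and the interaction, which is the challenge effect in the knockout minus that in the wild type. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. With 4 arrays against 4, the smallest two-sided exact permutation p is 0.0286, and the chance that such groups do not overlap is 2.86%. Where exact permutation p are given, they come from all relabellings of the 8 arrays concerned.

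Gene sets were 38 lists chosen before the data were examined. They covered allergic and immune cell types, lung cell types, tissues that may be taken along with lung, stress and signalling responses, and genes related to the knockout. They were tested with limma's camera at a preset correlation of 0.01 on 1 probe per gene, the one with the highest mean, for 12648 genes. The adjusted p is Benjamini-Hochberg over the 38 lists of a contrast, and lists needed at least 5 tested members. Counts within a list use the adjusted p of all probes, and counts adjusted over the list alone use the members' p only. camera with a correlation estimated from the data and fry were run as alternatives. camera compares the members of a list with the other genes, whereas fry asks whether the members change at all.

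Genes are named by a rule. It takes Prdm11, the 8 largest changes in each direction among called probes whose groups do not overlap, with 1 symbol and 1 probe per gene, and for each list described up to 3 called members with the largest changes. Where no member was called, it takes the member with the smallest p. The condition on overlap was not applied to the interaction. Not every gene the rule names is printed, and a named gene may be given in other contrasts. Ccndbp1 and Mapkbp1 were chosen after their values were seen.

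Scores per array were the median log2 of the 1338 probes for olfactory, vomeronasal and bitter taste receptor genes, of which 640 were tested, and the mean log2 of the cardiac muscle, skeletal muscle and ribosomal protein lists. The score of the chromosome segment around Lrrc57 covers 60 probes of 49 genes, whose log2 deviations from the mean were weighted by the genotype effects in untreated mice, so that the untreated groups lie apart by construction. The receptor and segment scores were chosen after the arrays were seen.

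The alternatives were a floor of 32, quantile normalization of the log2 values, median centring, cyclic loess, no filter, a filter at the 60th percentile, eBayes with trend and robust, arrayWeights, 1 probe per gene, the 8 arrays of a comparison alone, non-overlap of the groups, and leaving out each of the 16 arrays. The replicate number was also fitted as a block. The receptor median and the skeletal muscle mean as covariates were added after the data were seen. For each comparison of 4 against 4, all 35 splits of its arrays were fitted beside the other 8, and for the interaction 100 relabellings of genotype within treatment were drawn. The replicate numbers were checked for pairing by correlating residuals of arrays with the same number, and pairs over 0.1 numbered 2, 0, 2 and 1 of 4 in the 4 comparisons, so the numbers were not treated as pairs. A sample far from its group was sought with the Dixon ratio, with a critical value of 0.829 for 4 values.

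The fit was tested on simulated data, with changes added to 67, 67 and 66 of 17810 probes. For challenge in wild type mice it recovered 32.8%, 76.1% and 93.9% of changes of log2 0.5, 1 and 2, with 8 false among 143 calls. For challenge in the knockout these were 28.4%, 62.7% and 95.5%, with 2 of 126 false. For genotype they were 23.9%, 83.6% and 98.5% with 7 of 144 false in untreated mice, and 20.9%, 79.1% and 98.5% with 9 of 141 false in challenged mice. For the interaction they were 5.97%, 55.2% and 87.9%, with 6 of 105 false. The simulated values were independent between probes, and each probe had the same spread on every array. The weights of the real arrays ran from 0.06 for challenged wild type replicate 4 to 2.86 for untreated knockout replicate 3. These rates need not hold for the real arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.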

Results

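Lung RNA from 16 female C57BL/6N mice was measured on Illumina bead arrays, with 1 array per mouse. The mice were wild type or carried a knockout of Prdm11, a gene of the PRDM family of transcriptional regulators, and were either untreated or challenged with ovalbumin (OVA), an egg-white protein that provokes allergic airway inflammation in sensitised mice. Each of the 4 groups held 4 mice. The untreated mice were 22 weeks old and the challenged mice 35 weeks old, so that every challenge comparison also holds the difference in age. In all, 17810 probes were bright enough to be tested, and the median intensity per array lay between 85.4 and 86.5. No probe was named Prdm11, so the targeted gene could not be checked and genotype rests on the labels. Challenged wild type replicate 4 stood apart from the rest, with correlations of 0.676 to 0.842 to the other arrays, while the lowest correlation between 2 other arrays was 0.877. The number of arrays limits the precision. Changes are given as log2 differences ± SE and levels as mean log2 intensity ± SD, with 4 mice per group.

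In wild type mice, OVA challenge was followed by higher expression of genes of mucus-producing airway cells and of alternatively activated macrophages, and by lower expression of alveolar type 1 and endothelial genes. Clca1, a secreted goblet cell protein, rose from 7.82 ± 1.64 to 12.42 ± 1.27, a change of 4.60 ± 0.91 or 24.3-fold (limma, adjusted p = 0.0021). Untreated replicate 3 stood at 10.27 and the others at 6.88 to 7.22, so that 1 mouse raised the untreated mean and lowered the fold. The anion exchanger Slc26a4 rose by 3.36 ± 0.41 and the trefoil peptide Tff2 by 1.91 ± 0.48. Of 16 measured goblet cell and mucus genes, 9 rose, 0 fell and 7 did not pass, and 9 rose when adjusted over the list alone (camera adjusted p = 0.000171; adjusted p = 0.355 with an estimated correlation). Among the alternatively activated macrophage genes, 11 of 21 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 9.88e-05, and adjusted p = 0.422 with an estimated correlation). They were led by Retnla at 4.27 ± 0.49, the macrophage elastase Mmp12 at 4.07 ± 0.65 and the ribonuclease gene Rnase2a at 3.97 ± 0.73. The chitinase-like gene Chil4 rose by 2.45 ± 0.72, a call that was lost without untreated replicate 1 or challenged replicate 1 (adjusted p up to 0.0591), and the chemokine Ccl9 by 2.38 ± 0.52.

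Lymphocyte and antigen presentation genes were also higher in challenged wild type lungs. The plasma cell gene Mzb1 rose by 2.31 ± 0.35 and the B cell receptor component Cd79a by 1.47 ± 0.45, and 10 of 22 B cell and plasma cell genes rose with 0 lower (10 and 0 adjusted over the list alone; camera adjusted p = 0.000261, and adjusted p = 0.422 with an estimated correlation). Of 21 T cell genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 0.000192, and adjusted p = 0.422 with an estimated correlation). Cd6 rose by 1.13 ± 0.29 and Bcl11b by 1.00 ± 0.23. Of 24 dendritic cell and MHC class II genes, 14 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 8.33e-06, and adjusted p = 0.355 with an estimated correlation). The class II gene H2-Eb1 rose by 1.18 ± 0.17 and the protease gene Ctss by 1.68 ± 0.18. Of 45 cell cycle genes, 16 rose and 2 fell (16 and 2 adjusted over the list alone; adjusted p = 0.000262, and adjusted p = 0.355 with an estimated correlation). Uhrf1 rose by 1.56 ± 0.17 and Birc5 by 1.19 ± 0.18. Of 20 monocyte and interstitial macrophage genes, 6 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0273, and adjusted p = 0.422 with an estimated correlation). The complement gene C1qb rose by 1.37 ± 0.28. The mast cell and basophil list gave the same adjusted p = 0.0273 with 5 of 11 higher and 1 lower, both with and without the adjustment over the list alone, and adjusted p = 0.422 with an estimated correlation. The mast cell protease gene Cpa3 rose by 1.02 ± 0.22. The monocyte call was lost without untreated replicate 4 or challenged replicates 1 or 3 of the wild type (adjusted p up to 0.0736), and the mast cell call without challenged wild type replicate 1 or challenged knockout replicate 3 (up to 0.0571) and with no filter (0.0616). Cd79a lost its call in 5 of 16 fits without 1 array (adjusted p up to 0.0579).

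The genes that fell in challenged wild type lungs included those of the gas-exchange surface and of vessels. Npnt, which encodes the basement membrane protein nephronectin, fell by 2.68 ± 0.32, Pon1 by 2.24 ± 0.30, the growth factor gene Fgf7 by 2.21 ± 0.20, the endothelial angiopoietin receptor Tek by 2.18 ± 0.57 and the collagen cross-linking enzyme Lox by 2.06 ± 0.23. Of 19 alveolar type 1 cell genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone; camera adjusted p = 8.33e-06, and adjusted p = 0.422 with an estimated correlation). Krt7 fell by 1.62 ± 0.44 and Emp2 by 1.51 ± 0.32. Of 36 endothelial cell genes, 19 fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 8.33e-06, and adjusted p = 0.422 with an estimated correlation). The lymphatic marker Lyve1 fell by 1.57 ± 0.32 and Tmem100 by 1.65 ± 0.39. Of 23 smooth muscle genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone; adjusted p = 0.0235, and adjusted p = 0.422 with an estimated correlation). Pdgfrb, a receptor of pericytes and fibroblasts, fell by 1.52 ± 0.25. That list's call was lost without challenged replicate 3 (adjusted p = 0.0985). On the challenged arrays Npnt lay above the array's 40th percentile in 1 of 4 mice and Fgf7 in 0 of 4, so their falls are lower bounds.

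Markers of striated muscle rose in the same comparison. Of 27 cardiac muscle genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone; camera adjusted p = 8.33e-06, and adjusted p = 0.422 with an estimated correlation). The ventricular myosin light chain Myl2 rose by 3.70 ± 0.87 and the atrial peptide Nppa by 2.44 ± 0.86. Of 22 skeletal muscle genes, 13 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 0.000171, and adjusted p = 0.504 with an estimated correlation). The slow troponin Tnnt1 rose by 2.97 ± 0.71. The mean over the skeletal muscle genes was 8.70 ± 0.32 in untreated and 9.79 ± 1.03 in challenged wild type lungs. Of 16 pairs of arrays 13 were higher for challenge (exact permutation p = 0.114, and 0.152 after Benjamini-Hochberg over 16 tests). Challenged replicate 3 stood at 8.46, within the untreated range of 8.22 to 8.90, so the rise did not hold for every mouse. Of 53 ribosomal protein genes, 27 rose and 3 fell (30 and 3 adjusted over the list alone; adjusted p = 1.26e-05, and adjusted p = 0.422 with an estimated correlation). Rpl7a rose by 0.99 ± 0.16. The largest of these rises, Rpl3l at 1.98 ± 0.40, belongs to a paralog expressed in striated muscle. Myl2, and Rnase2a among the macrophage genes, lay above the 40th percentile in 0 of 4 untreated mice, so their rises are lower bounds. Markers of eosinophils, the granulocytes of allergic inflammation, were tested for 5 of the 16 listed genes. Of these, 2 rose, Prg2 by 0.89 ± 0.27 and Epx by 0.29 ± 0.10 (4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.136). The eosinophil list did pass in at least 1 of the alternatives other than leaving out 1 array. Without 1 array the calls of Nppa, Epx and Prg2 were lost in 11, 13 and 1 of 16 fits (adjusted p up to 0.142, 0.122 and 0.0519), and the skeletal muscle list did not pass in fry (adjusted p = 0.0515).

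In all, 5244 probes were called in challenged against untreated wild type mice (limma, Benjamini-Hochberg adjusted p under the threshold of 0.05), 2086 higher and 3158 lower, of which 310 and 703 changed at least 2-fold. Of the 38 gene lists, 14 passed. The 640 tested probes of chemosensory receptor genes, a group chosen after the values were seen because these genes belong to sensory tissues, were called higher in 111 cases and lower in 0 (median 0.24), and went the other way with challenge in mice labelled knockout (7 higher and 22 lower, median -0.15). The count was 3256 without untreated replicate 1 and 2084 when the 8 arrays of these groups were fitted alone. It was 1296 with the receptor median and 1634 with the skeletal muscle mean of each array as a covariate, alternatives chosen after the data were seen, and the median absolute log2 change of the 5244 probes went from 0.69 to 0.37 and 0.63.

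**Figure D1:**
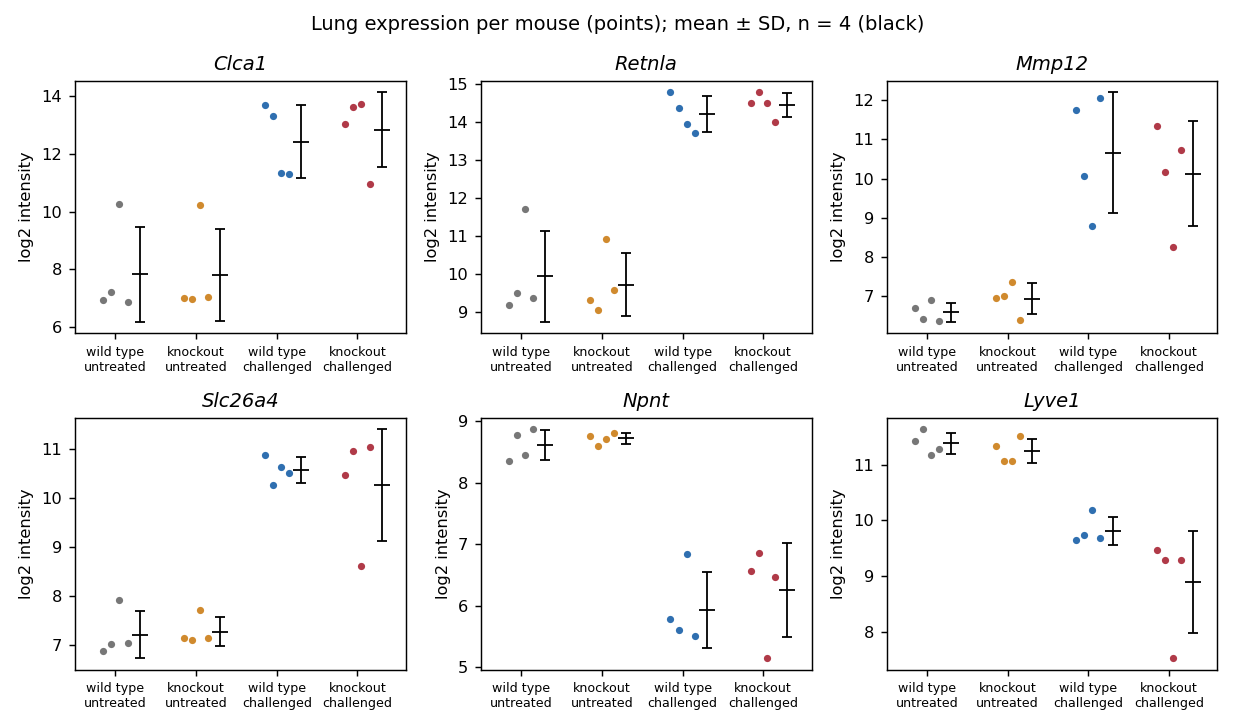
Log2 intensity of 6 genes in the 4 groups of mice, with 1 point per mouse and the mean ± SD in black (n = 4). Clca1, Retnla, Mmp12 and Slc26a4 were higher and Npnt and Lyve1 lower in both challenged groups, and 1 untreated mouse of each genotype (replicate 3) had Clca1 well above the other three.

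In mice labelled knockout, challenge moved many of the same groups of genes, while the smooth muscle list and the mast cell and basophil list did not pass in camera here (adjusted p = 0.352 and 0.992) or in the interaction, the test of a difference between the genotypes (0.351 and 0.171). Clca1 rose by 5.03 ± 0.91 or 32.6-fold (limma, adjusted p = 0.0014), the secreted mucin Muc5ac by 2.78 ± 0.66 and Slc26a4 by 2.99 ± 0.41. For Clca1, untreated knockout replicate 3 stood at 10.22 and the others at 6.96 to 7.02, which lowered the fold. Of 16 goblet cell and mucus genes, 12 rose and 1 fell (13 and 2 adjusted over the list alone; camera adjusted p = 7.62e-08, and adjusted p = 0.0682 with an estimated correlation). Of 21 alternatively activated macrophage genes, 13 rose and 0 fell (14 and 0 adjusted over the list alone; adjusted p = 7.44e-08, and adjusted p = 0.204 with an estimated correlation). Retnla rose by 4.73 ± 0.49, Rnase2a by 3.36 ± 0.73, Chil4 by 3.34 ± 0.72 and Mmp12 by 3.19 ± 0.65. Of 25 chemokines, 8 rose and 1 fell (12 and 2 adjusted over the list alone; adjusted p = 0.00116, and adjusted p = 0.291 with an estimated correlation). Ccl8 rose by 2.08 ± 0.54 and the neutrophil attractant Cxcl1 by 1.40 ± 0.20.

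Of 21 T cell genes, 11 rose and 0 fell in the mice labelled knockout (15 and 0 adjusted over the list alone; camera adjusted p = 5.38e-07, and adjusted p = 0.322 with an estimated correlation). Bcl11b rose by 1.84 ± 0.23 and the T cell receptor component Cd3d by 1.71 ± 0.50. Of 22 B cell and plasma cell genes, 11 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 4.47e-05, and adjusted p = 0.219 with an estimated correlation). Mzb1 rose by 2.22 ± 0.35 and Cd79a by 2.20 ± 0.45. Of 24 dendritic cell and MHC class II genes, 17 rose and 0 fell (20 and 0 adjusted over the list alone; adjusted p = 2.86e-10, and adjusted p = 0.0844 with an estimated correlation). Ctss rose by 1.59 ± 0.18 and H2-Ob by 1.51 ± 0.38. Of 45 cell cycle genes, 21 rose and 0 fell (23 and 0 adjusted over the list alone; adjusted p = 3.57e-11). Uhrf1 rose by 1.45 ± 0.17, the mitotic activator Cdc20 by 1.30 ± 0.16 and Prc1 by 1.21 ± 0.19. This was the list that passed with an estimated correlation (adjusted p = 0.00704). Of 20 monocyte and interstitial macrophage genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0165, and adjusted p = 0.423 with an estimated correlation). C1qa rose by 1.04 ± 0.29. This call was lost without challenged knockout replicates 1 or 4 (adjusted p up to 0.0594). Without 1 array the calls of Ccl8, Cd3d, H2-Ob and C1qa were lost in 2, 5, 1 and 3 of 16 fits (adjusted p up to 0.0557, 0.0976, 0.0506 and 0.0780).

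Alveolar type 1 and endothelial genes fell in challenged mice labelled knockout. Emp2 fell by 2.25 ± 0.32, the advanced glycation receptor gene Ager by 2.04 ± 0.45 and the tight junction gene Cldn18 by 1.79 ± 0.36, and 14 of 19 alveolar type 1 cell genes fell with 0 higher (15 and 0 adjusted over the list alone; camera adjusted p = 8.63e-11, and adjusted p = 0.204 with an estimated correlation). Of 36 endothelial cell genes, 26 fell and 0 rose (30 and 0 adjusted over the list alone; adjusted p = 3.91e-16, and adjusted p = 0.204 with an estimated correlation). Tmem100 fell by 2.54 ± 0.39, Lyve1 by 2.35 ± 0.32 and the capillary carbonic anhydrase Car4 by 2.21 ± 0.27. Hpgd, which degrades prostaglandins, fell by 2.64 ± 0.44, and Npnt fell by 2.46 ± 0.32 to a level above the 40th percentile in 3 of 4 mice. Of 19 glucocorticoid-responsive genes, 7 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.0254, and adjusted p = 0.423 with an estimated correlation). The phosphatase gene Dusp1 fell by 1.86 ± 0.27. Of 36 antioxidant and xenobiotic genes, 9 fell and 2 rose (12 and 2 adjusted over the list alone; adjusted p = 0.024, and adjusted p = 0.423 with an estimated correlation). The cytochrome P450 gene Cyp4b1 fell by 2.05 ± 0.33 and Cyp2b10 by 1.93 ± 0.21. The glucocorticoid call was lost without challenged knockout replicate 3 (adjusted p = 0.0527) and the antioxidant call without challenged knockout replicate 4 (adjusted p = 0.103).

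Each of the 22 skeletal muscle genes rose in the mice labelled knockout (22 and 0 adjusted over the list alone; camera adjusted p = 1.13e-15, and adjusted p = 0.204 with an estimated correlation). Tnnt1 rose by 3.21 ± 0.71 and parvalbumin, Pvalb, by 2.87 ± 0.53. Of 27 cardiac muscle genes, 19 rose and 0 fell (23 and 0 adjusted over the list alone; adjusted p = 3.39e-14, and adjusted p = 0.204 with an estimated correlation). Myl2 rose by 5.17 ± 0.87, a lower bound since it lay above the 40th percentile in 0 of 4 untreated mice. Of 20 adipose tissue genes, 6 rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 0.000735, and adjusted p = 0.423 with an estimated correlation). Cox8b, which is also on the cardiac list, rose by 2.80 ± 0.42 and the brown fat gene Ucp1 by 1.62 ± 0.53, a call lost in 12 of 16 fits without 1 array (adjusted p up to 0.130). Of 53 ribosomal protein genes, 18 rose and 1 fell (25 and 2 adjusted over the list alone; adjusted p = 1.16e-06, and adjusted p = 0.423 with an estimated correlation). Rpl19 rose by 0.84 ± 0.18. The mean over the skeletal muscle genes was 8.85 ± 0.29 in untreated and 10.88 ± 0.32 in challenged mice labelled knockout.

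For challenge in mice labelled knockout, 2954 probes were called, 1621 higher and 1333 lower, of which 406 and 292 changed at least 2-fold, and 16 of the 38 lists passed. The count was 5424 without challenged wild type replicate 4, which enters the shared estimate of spread, and 95 with the mean of the skeletal muscle genes as a covariate, an alternative chosen after the data were seen. With that covariate the median absolute log2 change of the 2954 probes went from 0.68 to 0.58 and their median SE from 0.150 to 0.253. On the untreated knockout arrays Ccl8 and Ucp1 lay above the 40th percentile in 0 of 4 mice and Rnase2a and Muc5ac in 1 of 4, so their rises are lower bounds. Which direction held more probes depended on the setting, with 2575 higher and 2849 lower without challenged wild type replicate 4, 3160 and 3888 with arrayWeights, 2720 and 3098 with the 8 arrays alone and 1731 and 2429 with the receptor median as a covariate.

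**Figure D2:**
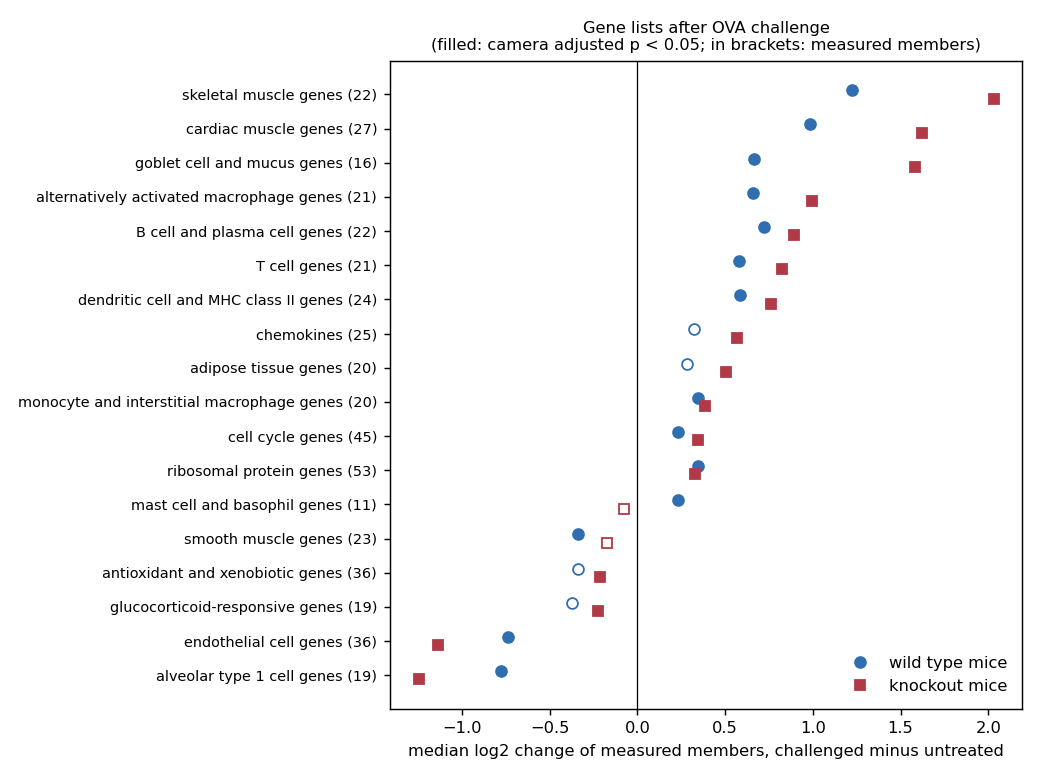
Median log2 change after challenge for each list that passed in at least 1 genotype, with wild type mice as circles and mice labelled knockout as squares, filled where camera's adjusted p was under 0.05. The medians of the alveolar type 1 list were -0.78 and -1.25 and those of the goblet cell list 0.67 and 1.58, for wild type and knockout.

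Across the 12648 genes, the challenge effects in the genotypes correlated with Pearson r = 0.43 and Spearman rho = 0.21, as a description across genes, which are not independent replicates. Among all tested probes, with several for some genes, 558 rose in both genotypes where independent lists would share 190. In the same count 797 fell in both against 236, and 102 were called in opposite directions against 444. These comparisons share no arrays, but they share the estimate of spread of each probe and the difference in age. The shared spread can raise the overlap in either direction, and age can move genes alike in both genotypes. The excess over independent lists therefore does not measure a shared response to challenge alone. Without challenged wild type replicate 4 the correlation was 0.58.

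Between untreated mice, genotype was compared at 22 weeks to ask what the knockout changed in the unchallenged lung, and 3 probes differed. Lrrc57, which encodes a leucine-rich repeat protein, was lower in the mice labelled knockout at 6.49 ± 0.08 against 7.77 ± 0.04, a difference of -1.28 ± 0.13 (limma, adjusted p = 0.00045). Rmdn3, which encodes a protein that tethers mitochondria to the endoplasmic reticulum, differed by -1.13 ± 0.16 (adjusted p = 0.032), and the other probe of that gene gave -0.32 ± 0.14 and was not called, nor was it in challenged mice (-0.13 ± 0.14, the same sign). Tmem87a, which encodes a Golgi membrane protein, was higher by 1.56 ± 0.23 (adjusted p = 0.036). These genes lie on the chromosome that carries Prdm11, which holds 7.74% of the tested probes and 8 of the 12 probes with groups that did not overlap and an unadjusted p under 0.001 in this comparison. Each value has all 4 mice of a genotype above or below the 4 of the other. Lrrc57 kept its call without any 1 array, whereas Rmdn3 and Tmem87a each lost theirs in 10 of 16 such fits (adjusted p up to 0.221 and 0.225) and with cyclic loess or the replicate number as a block.

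Immune and lung cell type genes showed no call between the untreated genotypes. Of 16 goblet cell and mucus genes, 24 genes neighbouring Prdm11 and 8 PRDM family genes, 0 were called, and the smallest p in these lists belonged to Tff3 at 0.13 ± 0.12, Trp53i11 at 0.22 ± 0.11 and Zfpm1 at 0.11 ± 0.12, with Tff3 above the 40th percentile in 0 of 4 wild type mice. camera nevertheless placed 5 lists higher in mice labelled knockout, each with 0 members called, and fry placed 0. They were the erythroid list (median 0.12, adjusted p = 0.000187; 2 higher adjusted over the list alone; adjusted p = 0.306 with an estimated correlation), cardiac muscle (median 0.31, adjusted p = 0.000187; adjusted p = 0.986 with an estimated correlation), cell cycle (median 0.06, adjusted p = 0.00318; adjusted p = 0.306 with an estimated correlation), ribosomal protein (median 0.09, adjusted p = 0.00385; adjusted p = 0.986 with an estimated correlation) and immediate early genes (median 0.05, adjusted p = 0.00792; adjusted p = 0.625 with an estimated correlation). Their members with the smallest p were Hbb-b2 at 0.80 ± 0.26, Cox6a2 at 0.54 ± 0.27, Pcna at 0.62 ± 0.18, Rpl38 at 0.52 ± 0.17 and Per1 at 0.71 ± 0.20, none of which passed. Leaving out 1 array ended the cardiac, ribosomal and immediate early calls (adjusted p up to 0.110 without untreated wild type replicate 3, 0.395 without untreated knockout replicate 2 and 0.393 without untreated wild type replicate 1). At an unadjusted p under 0.05, 327 probes separated the genotypes, and the groups did not overlap for 4.26% of probes, where chance gives 2.86%. Of the called probes 1 was higher and 2 lower, against 17 and 7 with arrayWeights and 7 and 6 with the 8 arrays alone.

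**Figure D3:**
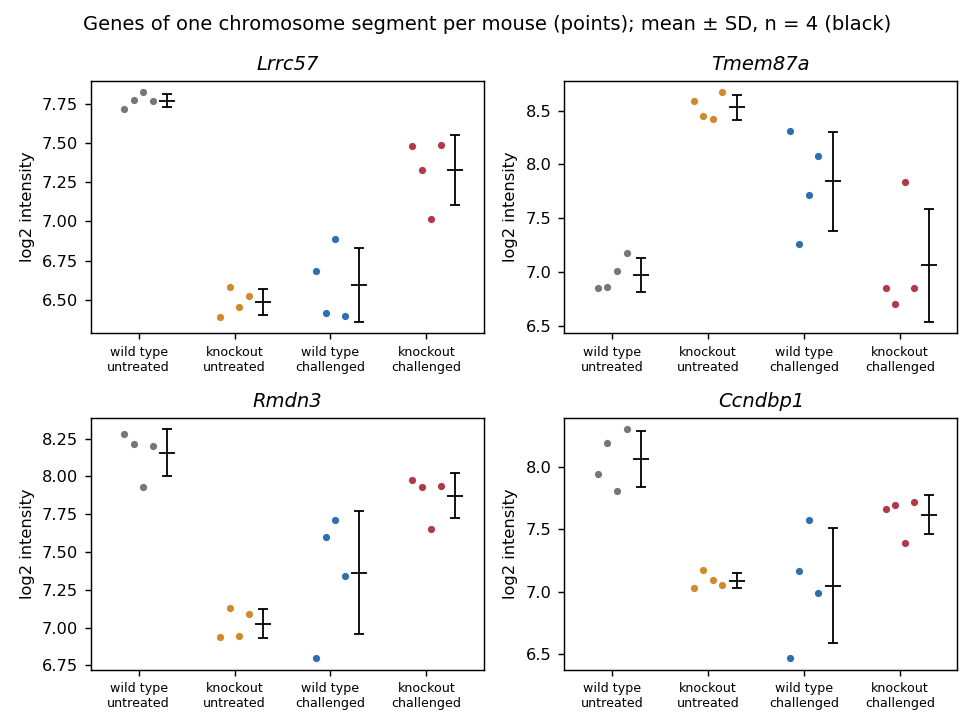
Log2 intensity of Lrrc57, Tmem87a, Rmdn3 and Ccndbp1, which lie near one another on the chromosome of Prdm11, with 1 point per mouse and the mean ± SD in black (n = 4). Mice labelled knockout were lower for Lrrc57 when untreated (6.49 against 7.77) and higher when challenged (7.33 against 6.59).

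Between challenged mice, 7879 probes differed by genotype label, 3764 higher and 4115 lower in mice labelled knockout (limma). Which direction held more probes depended on the setting, with 3915 higher and 3589 lower with cyclic loess, 2789 and 2464 with the filter at the 60th percentile, 1964 and 1372 with the 8 arrays alone and 2737 and 2536 with the muscle covariate. Genes of contractile and energy metabolism of striated muscle were among the highest, with the fast myosin heavy chain Myh4 at 2.23 ± 0.48, muscle glycogen phosphorylase Pygm at 1.97 ± 0.29 and the muscle carnitine palmitoyltransferase Cpt1b at 1.74 ± 0.24. Of 22 skeletal muscle genes, 9 were higher and 0 lower (11 and 0 adjusted over the list alone; camera adjusted p = 0.00186, and adjusted p = 0.979 with an estimated correlation), and of 27 cardiac muscle genes 9 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.00916, and adjusted p = 0.979 with an estimated correlation). Hspb7 differed by 1.84 ± 0.45 and Tnni3 by 1.61 ± 0.34. Of 36 endothelial cell genes, 16 were lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 0.0127, and adjusted p = 0.979 with an estimated correlation). Car4 differed by -1.43 ± 0.27, Ramp2 by -1.24 ± 0.33 and von Willebrand factor, Vwf, by -1.14 ± 0.38. Of 45 cell cycle genes, 18 were higher and 7 lower (18 and 8 adjusted over the list alone; adjusted p = 0.0367, and adjusted p = 0.979 with an estimated correlation). Cdc20 differed by 1.31 ± 0.16, Cdca8 by -1.24 ± 0.28 and Tyms by -1.23 ± 0.29. Without challenged wild type replicate 3, 0 of these 4 lists passed (cardiac adjusted p = 0.154, skeletal 0.0880), the endothelial call was also lost without challenged knockout replicate 3 (0.156), and the cell cycle call was lost without any of 5 of the arrays (up to 0.142). The cardiac call was lost without challenged knockout replicate 3 as well, and Vwf lost its call without challenged wild type replicate 3 (0.0530). With the replicate number as a block or with no filter the cell cycle list did not pass (adjusted p = 0.0556 and 0.0799), and in fry the endothelial, cardiac and skeletal lists did not (0.138, 0.155 and 0.117).

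Mucus and type 2 genes did not separate the challenged groups as lists. Of all 17810 tested probes 7879 were called in this comparison, 3764 higher and 4115 lower. Called members, or a small p in fry, therefore do not by themselves single out any of the following lists. Of 16 goblet cell and mucus genes 4 were higher and 2 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.534). The regulator Foxa3 was higher by 1.14 ± 0.27, and Clca1 stood at 12.83 ± 1.30 in mice labelled knockout against 12.42 ± 1.27. Of 11 genes of Th2 cytokines and receptors 1 was higher and 2 lower (1 and 2 adjusted over the list alone; adjusted p = 0.953). The signalling gene Stat6 differed by 1.10 ± 0.19 and the decoy receptor Il13ra2 by -0.88 ± 0.24. Of 11 mast cell and basophil genes 1 was higher and 5 lower (1 and 6 adjusted over the list alone; adjusted p = 0.153, and fry adjusted p = 0.00581). Cpa3 differed by -1.22 ± 0.22 and Cd200r3 by -1.10 ± 0.16. Of 19 circadian clock genes 9 were higher and 3 lower (9 and 3 adjusted over the list alone; adjusted p = 0.153, and fry adjusted p = 0.00349). Nr1d2 differed by 1.68 ± 0.35, Per2 by 1.46 ± 0.21 and Dbp by 1.43 ± 0.20. Of 8 PRDM family genes 1 was higher and 5 lower (1 and 5 adjusted over the list alone; adjusted p = 0.343, and fry adjusted p = 0.00581). Prdm10 differed by -0.97 ± 0.16 and the plasma cell regulator Prdm1 by -0.80 ± 0.16. Of 24 genes neighbouring Prdm11 8 were higher and 1 lower (8 and 1 adjusted over the list alone; adjusted p = 0.355). Acp2 differed by 1.19 ± 0.21 and Pex16 by 1.18 ± 0.17. Stat6 and Cpt1b on the challenged wild type arrays and Il13ra2 on those labelled knockout lay above the 40th percentile in 0 of 4 mice, so their differences are lower bounds.

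Dim probes moved with the genotype label on the challenged arrays. Of the 640 chemosensory receptor probes, 385 were lower and 12 higher in mice labelled knockout, with a median difference of -0.43. These probes had passed a filter that the 4 arrays of 1 group could meet alone. Their selection may thus favour probes that were bright on the challenged wild type arrays. The median log2 of all receptor probes was 6.18 ± 0.08 on challenged wild type arrays and 5.99 ± 0.04 on challenged arrays labelled knockout, with 0 of 16 pairs of arrays higher for the knockout (exact permutation p = 0.0286, the smallest that 4 against 4 can give, two-sided; 0.0762 after Benjamini-Hochberg over 16 tests). It was 6.08 ± 0.04 and 6.06 ± 0.03 on the untreated arrays. The largest falls in mice labelled knockout included the testis gene Ctcfl at -2.24 ± 0.58 and the adrenal and gonadal regulator Nr0b1 at -1.91 ± 0.36. Actb fell by 2.69 ± 0.52 at 1 of its 5 probes, of which 2 were called. Whether genes of other tissues were frequent among the falls was not tested. Ccdc144b was higher by 2.32 ± 0.19. With the receptor median of each array as a covariate, an alternative chosen after the data were seen, 197 probes were called, of which 62 were among the 7879, 61 with the same sign and 1 with the opposite sign, and 3336 probes were called when the 8 arrays were fitted alone.

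The question of whether the response to challenge differs between the genotypes was tested as an interaction, in which 1662 probes were called, 1009 with a larger or more positive challenge effect in mice labelled knockout and 653 with a smaller or more negative one. The split was 1187 and 464 with cyclic loess, but 1809 and 1856 with arrayWeights and 1337 and 1388 without challenged wild type replicate 4. The skeletal muscle genes had the more positive effect, by a median of 0.90 (2 of 22 higher and 0 lower, 2 and 0 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.951 with an estimated correlation). Pygm had an interaction of 2.06 ± 0.40 and Myh4 of 2.31 ± 0.68. Myh4 lost its call in 13 of the 16 fits without 1 array (adjusted p up to 0.0944). The endothelial cell genes had the more negative effect, by a median of -0.42 (1 of 36 lower and 0 higher, 1 and 0 adjusted over the list alone; adjusted p = 0.027, and adjusted p = 0.951 with an estimated correlation). Car4 had an interaction of -1.85 ± 0.38, and stood at 8.42 ± 0.74 in challenged mice labelled knockout and at 9.85 ± 0.31 in challenged wild type mice. Without challenged wild type replicate 3 both list calls were lost (adjusted p = 0.215 for each), and the endothelial call was also lost without untreated knockout replicate 1 or challenged knockout replicate 3. Neither list passed in fry (adjusted p = 0.534 for each).

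Single genes with opposite responses included those that differed between untreated mice. By label, Lrrc57 fell with challenge in wild type mice and rose in knockout mice, an interaction of 2.01 ± 0.18 (limma, adjusted p = 0.0001). Tmem87a had one of -2.34 ± 0.33 (limma, adjusted p = 0.0069). For both genes the genotype difference had opposite signs in untreated and challenged mice. Exchanged genotype labels in 1 treatment, or a passenger segment segregating apart from the knockout, would also give this, and both stay open. The complement regulator Cd59a was at 1.99 ± 0.42, the sphingomyelin synthase Sgms1 at 1.85 ± 0.35 and the clock gene Per2 at 1.53 ± 0.30. Cd59a also changed sign, knockout minus wild type by label. It was at -0.73 ± 0.30 in untreated mice, where it was not called, and at 1.26 ± 0.30 in challenged mice. The haemoglobin genes Hbb-bt and Hba-a1 had the more negative challenge effect in mice labelled knockout, with interactions of -1.38 ± 0.22 and -1.26 ± 0.23, and of -1.37 ± 0.26 for the haem synthesis gene Alas2. Of 11 erythroid genes 1 was higher and 3 lower (1 and 5 adjusted over the list alone; camera adjusted p = 0.109). Of 16 goblet cell and mucus genes 2 were higher and 2 lower (4 and 2 adjusted over the list alone; adjusted p = 0.507), and the interaction for alternatively activated macrophage genes gave 1 higher and 1 lower of 21 (1 and 1 adjusted over the list alone; adjusted p = 0.808). Challenged arrays of the genotypes differed in the receptor probes as given above, and with the receptor median as a covariate 3 probes were called for the interaction. The count was 410 without untreated wild type replicate 1, which was the lowest, and 3611 without challenged wild type replicate 3, which was the highest. It also moved by more than 1.5 times without any of 11 other arrays.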

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

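Within groups of 4 mice, 188 sets of values were searched for a sample far from the other three, and 19 were found where chance gives about 5 percent. A sample was marked when its gap to the next was a large part of the range (Dixon ratio). In untreated wild type mice, replicate 3 stood apart for Clca1 (0.899), Retnla (0.872) and Slc26a4 (0.849), replicate 1 for Gucy1b1 (0.854) and replicate 4 for Eddm3b (0.889). In untreated knockout mice, replicate 3 stood apart for Clca1 (0.980), Slc26a4 (0.920) and Nfic (0.844), and replicate 1 for Ndrg2 (0.838) and for the receptor probe median (0.884). In challenged wild type mice, replicate 4 stood apart for its median correlation with the other arrays (0.871) and for Nfic (0.965), Tnfrsf10b (0.886) and Fam228b (0.903). In challenged mice labelled knockout, replicate 2 stood apart for the cardiac muscle mean (0.901), and replicate 3 for the segment score (0.916), Tmem87a (0.867), Rmdn3 (0.871) and Pamr1 (0.964).

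A challenge response that differed between the genotypes, by the interaction test of that difference in limma, marked further results. Apart from Lox, the genes are the 8 largest called interactions in each direction, named by that same test. Their marking was therefore fixed beforehand. Lox was added from 24 named challenge responses compared. The response was more positive in mice labelled knockout for Myh4 (2.31), Ccdc144b (2.26), Pygm (2.06), Lrrc57 (2.01), Cd59a (1.99), Cpt1b (1.86), Sgms1 (1.85), Pamr1 (1.78) and Lox (1.31), and for the median of the skeletal muscle genes (0.90). It was more negative for Mrps14 (-1.76), Nbeal1 (-1.76), Fam228b (-1.83), Tnfrsf10b (-1.83), Rnf182 (-1.84), Car4 (-1.85), Tmem87a (-2.34) and Actb (-2.47), and for the median of the endothelial cell genes (-0.42). Leaving out 1 array ended the call in 13 of 16 fits for Myh4 (adjusted p up to 0.0944), 11 each for Actb, Fam228b (0.0896) and Mrps14 (0.0917), 10 for Rnf182 (0.0799), 8 each for Tnfrsf10b (0.0736) and Lox (0.0649) and 1 for Nbeal1 (0.0503). The skeletal muscle list lost its call in 1 and the endothelial list in 3 such fits (up to 0.215). In the group where each was dimmest, Cpt1b lay above the array's 40th percentile in 0 and Pamr1 and Nbeal1 in 1 of 4 mice.

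Around Lrrc57, 27 of 60 probes, among them the 3 called by genotype in untreated mice, had the opposite sign in challenged mice and 33 the same sign (7 and 6 of the 13 with an unadjusted p under 0.05 in untreated mice), and the test of exchanged labels was chosen after this was seen. In other segments of 60 probes a median of 23 had the opposite sign, so the count of 27 alone does not mark this segment. Exchanged genotype labels in 1 of the treatments would turn the segment score, whose difference, challenged knockout minus wild type by label, was -0.16 (exact permutation p = 0.0857 over 70 relabellings). That value does not decide for or against an exchange, and the sources cannot settle it. Loss of contrast on the challenged wild type arrays stays open too: of 265 other segments 0 had as low a sum of products of the genotype effects, but 0 had untreated effects as large, so this comparison could not come out otherwise. A passenger segment that segregates apart from the knockout was not tested and stays open.

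Between the challenged groups 7879 probes differed, and the test of lost contrast was chosen after this was seen. Loss of contrast between dim and bright probes on the challenged wild type arrays is left open: the receptor median differed by -0.19, knockout minus wild type by label, but these probes prompted the test, and the gap came from both groups, with 0.10 for challenge in wild type and -0.07 in knockout (exact permutation p = 0.0571 for each). With that median as a covariate 197 probes were called, while the median SE rose from 0.158 to 0.245 and the median absolute log2 change went from 0.64 to 0.27. With the skeletal muscle mean as a covariate 5273 probes were called, and the median absolute log2 change went from 0.64 to 0.66. The median SE went from 0.158 to 0.197. These values argue against the amount of skeletal muscle as the sole cause. The score was built on the skeletal muscle list only, so admixture of cardiac or other tissue stays open. A genotype effect and an array effect cannot be told apart here.

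Cardiac and skeletal muscle genes were higher in challenged lungs, and the test of vein muscle was chosen after this was seen. The skeletal muscle genes varied together within groups, as muscle tissue taken along with part of the lung would have it, with a median pairwise correlation of 0.798 against a highest of 0.348 in 1000 random lists. The genes of ciliated cells, which belong to the lung, reached 0.583, so varying together does not single out tissue taken along. A rise in the heart-type muscle cells of the lung's veins alone would leave the skeletal muscle genes unmoved. In mice labelled knockout 22 of these genes rose, which argues against it there. That outcome was already known when the test was chosen, so the test adds nothing to it.

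For each comparison, the arrays were split anew to see how many probes other groupings of the same arrays call. In the comparisons of 4 against 4, every other split mixes the real groups and adds their difference to the spread. Low counts there do not show what a grouping of like arrays would call. An array effect between the groups would give the same outcome. The real grouping alone reached its count in each comparison of 4 against 4, as 1 of 35 splits, the fewest possible. The real counts were 5244, 2954, 3 and 7879, and the highest others were 258, 0, 0 and 176. For the interaction, 2 of 100 relabellings, the real one included, reached the real 1662, and the highest other was 3984. Besides the real one, 2 relabellings keep the challenged groups whole, and the highest of the rest was 2.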

How the results depend on the processing

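Among named genes and lists that were called, 0 turned direction under the alternatives run for them, which do not include the covariates. Among list tests that did not pass, the direction turned in 5 with fry, 10 with no filter, 2 with the block and 134 leaving out 1 array, and among named genes not called in 1 leaving out 1 array. The calls of all 429 values of named genes kept their side of the threshold under the floor of 32, median centring and quantile normalization, and those of all 190 list tests under median centring and quantile normalization. Of the probes called for genotype in challenged mice, 1 was called with the opposite sign with the receptor median as a covariate. The larger share of higher or lower probes turned for every comparison but challenge in wild type mice, as given in the report, and was 386 and 373 by non-overlap for genotype in untreated mice. Leaving out 1 array, 6166 values of named genes stayed the same, 682 became weaker and 16 stronger; for lists these were 2978, 30 and 32. The cause was not tested where a value moved, and the covariates were chosen after the data were seen.

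Probes called for challenge in wild type mice numbered 1296 with the receptor median and 1634 with the skeletal muscle mean as a covariate, 2084 with the 8 arrays alone, and 3256 (without untreated wild type replicate 1) to 6903 (without challenged wild type replicate 3) leaving out 1 array. There the median absolute log2 change of the 5244 probes called without a covariate went from 0.69 to 0.37 with the receptor median (median SE 0.167 to 0.173) and to 0.63 with the muscle mean (SE 0.206). For challenge in the knockout they numbered 7048 with arrayWeights, 95 with the muscle mean, 5818 with 8 arrays, 5938 by non-overlap, and 2095 (without untreated knockout replicate 4) to 5424 (without challenged wild type replicate 4). For genotype in untreated mice they numbered 1 with cyclic loess, 24 with arrayWeights, 13 with 8 arrays, 759 by non-overlap, and 1 to 4 leaving out 1 array. For genotype in challenged mice they numbered 197 with the receptor median, 3336 with 8 arrays, and 6389 to 8715 leaving out 1 array. For the interaction they numbered 3665 with arrayWeights, 3 with the receptor median, 1187 higher and 464 lower with cyclic loess against 1009 and 653, and 410 to 3611 leaving out 1 array; with the receptor median the median change of the 1662 went from 0.84 to 0.43 and the SE from 0.205 to 0.242. The correlation of the challenge effects ranged from 0.35 to 0.58.

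With the replicate number as a block, 5416, 2880, 1, 7858 and 1857 probes were called, and the cell cycle list lost its call for genotype in challenged mice (adjusted p = 0.0556). Residual correlations of arrays with the same number ran from -0.04 to 0.32, -0.06 to 0.09, -0.03 to 0.31 and -0.09 to 0.15 in the comparisons of 4 against 4. No arrays with different numbers were set beside them, so these values do not settle whether the numbers pair the arrays.

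With an estimated correlation, 0, 1, 0, 0 and 0 lists passed in the order challenge in wild type, challenge in knockout, genotype untreated, genotype challenged and interaction. With fry, 0 passed for genotype untreated and 0 for the interaction. Leaving out 1 array, 12 to 17, 15 to 18, 3 to 6, 0 to 5 and 0 to 5 passed, the lowest for the last pair without challenged wild type replicate 3. Alternatives for Prdm11 were not run, as no probe is named for it. Dim probes limit what signal over background can show.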

Other observations

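Some clock genes changed with challenge, while the list did not pass in the test of a difference between the genotypes. In wild type mice the clock repressors Per2 and Cry2 fell by 1.38 ± 0.21 and 1.18 ± 0.14 and Bhlhe40 rose by 1.17 ± 0.15 (limma), with Cry2 above the 40th percentile in 0 of 4 challenged mice; of 19 circadian clock genes 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0921, fry adjusted p = 0.00662). In mice labelled knockout Bhlhe40 rose by 1.87 ± 0.15 and Dbp by 1.18 ± 0.20, and 3 genes rose and 3 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.992). In the test of the difference, the interaction, 4 of the genes were higher and 0 lower (9 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.171). The hour at which the lungs were taken is not in the labels.

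The haemoglobin gene Hba-a1 fell by 1.25 ± 0.16 with challenge in mice labelled knockout (0 of 11 erythroid genes higher and 2 lower, 0 and 3 adjusted over the list alone; camera adjusted p = 0.129). Between challenged mice 2 erythroid genes were higher and 6 lower by label (3 and 6 adjusted over the list alone; camera adjusted p = 0.477, fry adjusted p = 0.0457), with Hbb-bt at -0.98 ± 0.16. Of the surfactant genes, Sftpd rose by 1.20 ± 0.16 and Sftpb fell by 1.49 ± 0.35 in mice labelled knockout.

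On the chromosome of Prdm11, values for further genes within the segment around Lrrc57, chosen after they were seen and not called in untreated mice, are as follows. Ccndbp1 was at -0.97 ± 0.18 in untreated and 0.57 ± 0.18 in challenged mice, knockout minus wild type by label. Mapkbp1 (0.78 and 0.45) had the same sign in both and was not called in challenged mice either (limma, adjusted p = 0.142). These picked genes do not give the balance of the segment, where 27 of 60 probes had the opposite sign and 33 the same. The segment score, weighted by the untreated genotype effects, was 0.14 ± 0.10 in challenged wild type mice and -0.02 ± 0.14 in challenged mice labelled knockout, with 14 of 16 pairs of challenged arrays lower for the knockout.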
